A study of Zea mays with 20 samples.

How the data were processed

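RNA from 20 maize samples in 7 groups was measured on 11 two-colour Agilent arrays with 60-base probes. Per the labels' protocols, the plants were of the B73 inbred line, RNA from laser-microdissected cells was extracted and amplified in 2 rounds, and the product was coupled to Cy3 or Cy5. Each sample is a single dye channel of an array, per the labels. In all, 9 arrays carried 2 of the samples in opposite dyes, and 2 channels carried no sample of this series and were not used. The arrays lay on 4 slides. Archesporial replicates 2 and 3 shared their arrays and slide 2 with early PMC replicates 2 and 3. Early PMC replicate 1, PMC replicates 2 and 3 and the 3 tapetal samples lay on slide 1. Mature pollen (always Cy5), seedling (always Cy3) and parenchyma lay on slide 3. The labels do not tie a sample to a plant or culture, so p-values measure the spread between these samples, which may be partly technical.

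Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1 with its protocol for 2-colour expression arrays. They hold deposited raw intensity values, the median pixel brightness of each spot and of its local background, as well as the software's own processed intensity, which is background-subtracted, detrended and dye-normalized. They also hold flags for spots well above background, saturated spots and outlier spots. The mean brightness is not in every file, so the median was used. The authors' value table was set against the scanner files spot by spot. In 18 of its 20 columns it held exactly the raw median intensity of a deposited channel, so its scale is linear, without background correction, centring or normalization. In 14 columns this was the channel of the same sample. The columns of tapetal replicates 1 and 3 each held the channel deposited for the other, and so did those of the 2 parenchyma samples. These exchanges stay within a group.

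The columns of archesporial replicate 1 and PMC replicate 1 matched none of the 20 channels labelled with a sample. They were not compared with the 2 channels that carried no sample. Those lay on slide 1, in Cy5 on the array of tapetal replicate 1 and in Cy3 on that of early PMC replicate 1. The labels give the same dyes to archesporial replicate 1 (Cy5) and PMC replicate 1 (Cy3). The scanner file labelled archesporial replicate 1 and PMC replicate 1, 1 shared array on slide 4, held other data. Its channels had Spearman correlations of at most 0.713 and 0.624 with the other samples of their own groups, over all spots, against at least 0.860 and 0.903 for the value table columns. The archesporial column correlated as highly, at up to 0.865, with early PMC samples. The planned design took every sample from its scanner file. For these 2 samples the value table was used in its place, a choice made after this check and before any comparison was tested. They have no background value or flag, their array and slide are unknown, and each was treated as an array of its own. Every comparison was also run with the deposited scanner file and without both samples.

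Background was corrected with normexp (offset 50) on the own channel of each sample. For the 2 value table samples normexp ran on the foreground alone. The 20 channels were then quantile normalized and expressed as log2 intensity. Control spots were removed after normexp, outlier-flagged spots were left out, and the spots of the 11 replicated probes were averaged, which left 43633 probes. A probe was tested if it was well above background in at least 2 of the 18 samples with flags, which 39497 were. Well above background means a signal over the background by more than 13 times an additive error term where the header states the multiple. No spot was saturated in the samples with flags. The features are named only by the array's probe identifiers. The files give a gene name for 0 probes, and the gene table supplied holds none of these identifiers. The gene lists fixed before the data were examined could therefore not be tested, and no list has a result. The step that represents a gene by 1 of its probes and its alternative fall away for the same reason. The rule for named genes, the largest changes with non-overlapping samples and a signal above background in every flagged sample of the higher group, was kept without its condition on a gene symbol. It was limited to 2 probes up and 2 down per comparison.

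The 8 comparisons were tested with limma 3.58.1 in R 4.3.3 (statmod 1.5.0, the data.table package, version 1.17.8). All 20 samples entered 1 linear model with group means and a dye term, array as a random block and moderated variances with an intensity trend. The model had 12 residual degrees of freedom, and the within-array correlation, estimated on 5000 probes, was 0.0183. The dye term passed the threshold for 2 of 39497 probes. Tests were two-sided with Benjamini-Hochberg adjustment over the probes tested, and the threshold was an adjusted p of 0.05. A probe not well above background in any flagged sample of a group has only a bound there. Its fold is then written as at least the mean of the brighter group over, per sample, the higher of its own signal and the dimmest signal well above background, both as means of normalized log2 values. Where only some flagged samples of the dimmer group were well above background, the fitted difference is given, part of which is against background signal. The bounds leave out the dye term, so they are open to dye bias. In some samples the dimmest such signal was 5.72, below the named probes' own signals, which then set the bound. Where a bound exceeded the fitted fold, the fitted difference is given in its place.

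Replicate numbers come from the labels. The check of pairing correlated the deviations of same-numbered samples from their group means. Only mature pollen and seedling, whose same-numbered samples share arrays, had every one of 3 pairs above 0.1, with correlations of 0.266 to 0.381. PMC and tapetal samples that shared an array had -0.334 (replicate 2) and -0.246 (replicate 3), while PMC replicate 2 with tapetal replicate 3 had 0.350 and PMC replicate 3 with tapetal replicate 2 had 0.258, all on slide 1. The single within-array correlation of the model does not describe this structure.

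The test was tried on simulated data with 200 of 39386 probes changed and no other difference. The simulated samples varied independently, without effects of array, slide or dye. The false calls therefore do not tell how the test behaves with the correlations between samples given above. For early PMC against archesporial cells, 31.0% of the probes changed 2-fold and 88.0% of those changed 4-fold were called, with 5 false calls. For PMC against tapetal cells the shares were 41.0% and 82.0%, with 3 false calls. For mature pollen against seedling they were 22.0% and 69.0%, with 4 false calls. Other background corrections, normalizations, filters, dye, array, slide and replicate terms, subsets of samples and the omission of each sample in turn were tried as alternatives. All but those named as added were fixed before the data were examined. The number of arrays limits the precision.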

Results

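Transcript levels were measured in 7 cell types or organs of maize that span the passage of male germinal cells from mitosis to meiosis. Archesporial cells, the dividing germinal cells that precede meiosis, came from anthers of 0.7 to 0.9 mm. Early pollen mother cells (early PMC) came from anthers of 1.2 to 1.5 mm, and pollen mother cells (PMC), the cells that undergo meiosis, from anthers of 1.8 to 2.0 mm. Tapetal cells, the nutritive layer of the anther wall that surrounds the germinal cells, were taken at the same anther length as PMC. Mature pollen at 75 days, parenchyma cells of 2-month-old plants and 14-day-old seedlings completed the set. Parenchyma had 2 samples and every other group had 3. For each probe named in a comparison, every sample of the higher group lay above every sample of the other.

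Between 61.1% and 77.5% of probes were well above background in the 18 samples with flags, lowest in mature pollen replicate 1 and tapetal replicate 2 and highest in the seedling samples. Probes above background in every flagged sample of a group numbered 26588 in archesporial cells (2 samples), 26103 in early PMC, 25411 in PMC (2 samples) and 25317 in tapetal cells. The counts were 24921 in mature pollen, 29298 in parenchyma (2 samples) and 31542 in seedling. They have no test and depend on the number of samples in a group and on the flag, and with a fixed floor mature pollen had 30146 and seedling 31720.

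Mature pollen stood apart in how its signal was distributed. The brightest 1% of probes (436) held 70.7% ± 0.862 (SD, n = 3) of the background-corrected signal there. The share was 32.7% ± 11.8 (SD, n = 3) in archesporial cells, 31.1% ± 3.16 (SD, n = 3) in early PMC and 36.2% ± 5.72 (SD, n = 3) in PMC. Tapetal cells had 32.3% ± 2.77 (SD, n = 3), parenchyma 29.3% ± 6.22 (SD, n = 2) and seedling 34.3% ± 1.93 (SD, n = 3). Every pollen sample lay above every sample of the other groups.

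**Figure D1:**
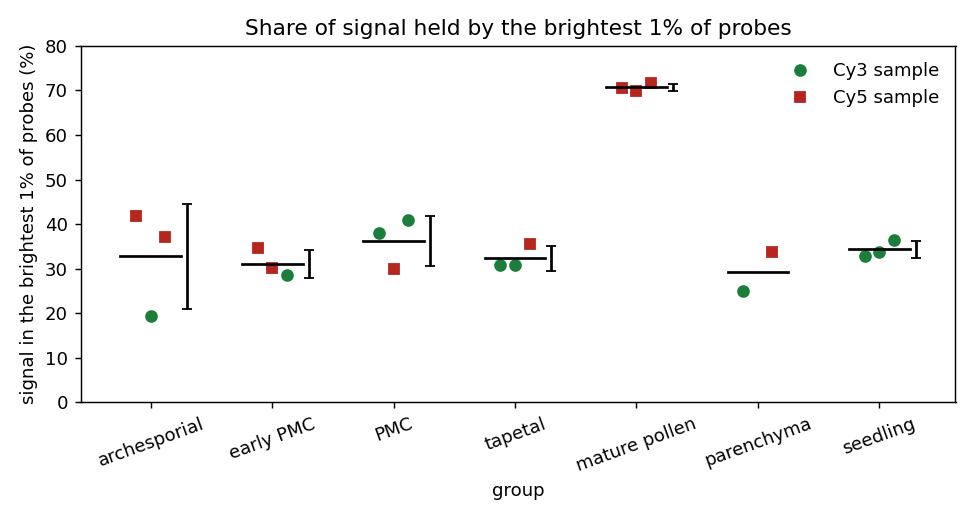
Percent of background-corrected signal held by the brightest 1% of probes (vertical axis) in each sample, by group (horizontal axis), with circles for Cy3 and squares for Cy5 samples, a line at each group mean and, for groups of 3, bars of 1 SD. The 3 mature pollen samples lie between 69.9% and 71.6%, and the highest sample of any other group is at 41.7%.

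The raw intensities ordered the groups along the same lines. Spearman correlations over all spots had a median of 0.943 within groups and 0.728 between groups. The germinal and tapetal samples had pairwise correlations of 0.799 or more between their groups. Mature pollen correlated with the other 6 groups at 0.555 to 0.649. Correlations between seedling and parenchyma samples were 0.782 to 0.831, and those between archesporial and seedling samples, at 0.716 to 0.812, overlapped this range and that of the germinal and tapetal samples. Archesporial replicate 1 correlated with the other archesporial samples at 0.860 to 0.861, while archesporial replicates 2 and 3, on slide 2, correlated with each other at 0.943. The correlations of archesporial replicate 1 with early PMC replicates 2 and 3, 0.863 and 0.865, were above those with its own group. With early PMC replicate 1 it had 0.824. Pairs of archesporial and early PMC samples reached 0.920, so the 2 stages overlapped in this measure.

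**Figure D2:**
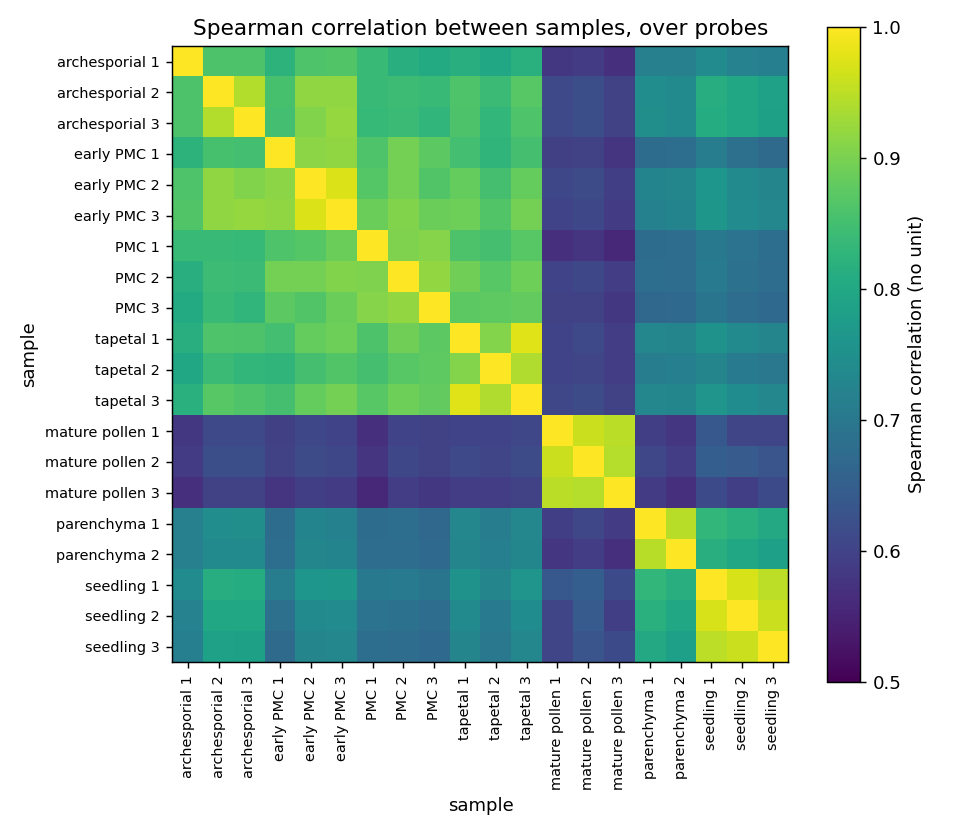
Spearman correlation (colour, no unit) between the raw intensities of each pair of the 20 samples in the authors' value table, with samples on both axes in the order of the groups. The 3 mature pollen samples correlate with each other at 0.944 to 0.959 and with all others at no more than 0.649, while the range of archesporial with seedling samples, 0.716 to 0.812, overlaps that of the germinal and tapetal samples, 0.799 or more between groups.

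The step from archesporial cells to early PMC covers the transition from mitotic to meiotic germinal cells. Early PMC had higher levels of 4903 probes and lower levels of 3552 than archesporial cells, 8455 of 39497 tested (21.4%; limma, adjusted p under 0.05). The median change was 1.19 log2 units among higher and -1.36 among lower probes, and 3316 and 2733 of them changed at least 2-fold. The largest increase by the naming rule was ZM_43391_1, with the sequence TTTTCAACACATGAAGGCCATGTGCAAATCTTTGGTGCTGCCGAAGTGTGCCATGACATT. Its log2 intensity was 7.74 ± 0.52 (SD, n = 3) in archesporial cells and 17.06 ± 0.68 (SD, n = 3) in early PMC, a log2 change of 9.32 ± 1.71 (SE, adjusted p = 0.001, limma). In PMC it was 17.37 in replicate 2 but 9.86 and 8.99 in replicates 1 and 3, and in tapetal cells it was 10.35 in replicate 2 but 18.54 and 18.25 in replicates 1 and 3. ZM_00818_1 rose by 7.15 ± 1.34 log2 units (SE, adjusted p = 0.0012, limma). ZM_09122_1 was lower in early PMC by a log2 change of -4.73 ± 0.30 (SE, adjusted p = 1.6e-07, limma), from 12.82 ± 0.29 to 8.09 ± 0.73 (SD, n = 3 each), and its levels in parenchyma (13.62) and seedling (12.11) were close to the archesporial one. ZM_42506_1 was lower by a log2 change of -4.88 ± 0.64 (SE, adjusted p = 7.8e-05, limma) from 17.47 ± 0.53 to 12.60 ± 0.21 (SD, n = 3 each). The calls of these 4 probes ended when only the 6 samples compared were fitted (adjusted p = 0.075 to 0.11, limma), at log2 changes of 9.5 for ZM_43391_1, 7.44 for ZM_00818_1, -4.89 for ZM_42506_1 and -4.85 for ZM_09122_1. Those of ZM_43391_1 and ZM_00818_1 also ended with slide as a term, at 8.91 and 6.53 (adjusted p = 0.079 and 0.086, limma), and that of ZM_00818_1 after loess and Aquantile, at 5.55 (adjusted p = 0.056, limma). Over the alternatives their adjusted p ranged from 2.7e-09 to 0.11.

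In this comparison the samples of the 2 groups did not overlap for 35.7% of probes, where chance gives 10% for 3 against 3. With slide as a term 7956 probes were called, and within slide 2, on 1 residual degree of freedom, 11536. The count was 2869 after loess and Aquantile, which leave out 4 samples and put the share of higher probes at 40% against 58%, 3775 with the deposited scanner file for archesporial 1 and PMC 1, and 1 when only the 6 samples compared were fitted, with 5917 at an unadjusted p under 0.05.

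From early PMC to PMC the germinal cells changed again. PMC had higher levels of 3516 probes and lower levels of 4064, 7580 of 39497 (19.2%; limma). Large increases outnumbered large decreases, with 272 probes at least 8-fold higher and 63 at least 8-fold lower. The counts were 964 and 743 on Agilent's processed signals, 126 and 58 with slide as a term, 69 and 25 with the deposited scanner file, 388 and 112 without PMC replicate 2, and 334 and 98 without early PMC replicate 1. ZM_41977_1, with the sequence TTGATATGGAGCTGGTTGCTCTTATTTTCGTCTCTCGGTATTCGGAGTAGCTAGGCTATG, was high in archesporial cells (16.53 ± 0.23) and early PMC (15.22 ± 0.81) and low in PMC (8.73 ± 0.46; SD, n = 3 each). Its log2 change from early PMC to PMC was -6.40 ± 0.36 (SE, adjusted p = 6.7e-08, limma). ZM_08960_1 had a log2 change of -5.84 ± 0.68 (SE, adjusted p = 2e-05, limma). ZM_42769_1 and ZM_43513_1 rose by 7.19 ± 1.41 and 6.62 ± 1.08 log2 units (SE, adjusted p = 0.0016 and 0.00039, limma), to levels of 16.23 and 13.81 in PMC, and tapetal cells had ZM_42769_1 at 16.30. ZM_43513_1 was at 15.75 and 15.78 in tapetal replicates 1 and 3 but at 9.31 in replicate 2. Early PMC replicate 1, on the slide of the PMC samples, had ZM_42769_1 at 12.71 against 6.82 and 7.43 in replicates 2 and 3, and with slide as a term its log2 change was 2.22 (adjusted p = 0.22, limma). The call of ZM_43513_1 also ended with slide as a term, at a log2 change of 5.79 (adjusted p = 0.19, limma). All 4 calls ended within slide 1, at 1.74 for ZM_42769_1, 6.25 for ZM_43513_1, -5.02 for ZM_41977_1 and -4.35 for ZM_08960_1, and with the deposited scanner file, at 3.73, 5.18, -5.37 and -3.92. Over the alternatives their adjusted p ranged from 3.6e-09 to 0.33.

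With slide as a term 4117 probes were called. Within slide 1, where early PMC has 1 sample assumed to vary like the other groups, limma called 0 of 39485, with 7755 at an unadjusted p under 0.05. Without early PMC replicate 3 the count was 4611, with the deposited scanner file 1651, with 75th percentile scaling 1346 and with equal summed signal 1294.

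Over the whole course from archesporial cells to PMC, 5719 probes were higher and 5716 lower, 11435 of 39497 (29.0%; limma). Among those changed at least 2-fold, the 4319 higher probes had covered a median of 47.0% (interquartile range 17.6% to 78.0%) of their log2 change by the early PMC stage and the 4439 lower ones 56.0% (23.9% to 83.0%). Of these, 2134 and 2072 were called at the step to early PMC. The shares use group means without a slide or dye term. Early PMC had samples on the slide of the flagged archesporial samples and on that of the flagged PMC samples. An effect of slide on the shares therefore cannot be told apart. The mean level of ZM_34020_1 rose from 8.40 ± 2.00 in archesporial cells through 12.80 ± 1.04 in early PMC to 17.29 ± 0.40 in PMC (SD, n = 3 each). Its log2 change was 8.88 ± 0.69 over the course (SE, adjusted p = 1.2e-07, limma), and no test of its single steps is given. Archesporial replicate 1, taken from the value table, had ZM_34020_1 at 10.69, against 7.02 and 7.47 in replicates 2 and 3. ZM_00841_1 rose by 9.05 ± 0.86 log2 units (SE, adjusted p = 8.8e-07, limma) and shares its last 20 bases with ZM_34020_1, so the signals of the 2 probes are not known to be independent. ZM_41977_1 and ZM_42506_1 were lower in PMC, with log2 changes of -7.70 ± 0.36 and -7.07 ± 0.66 (SE, adjusted p = 7.7e-10 and 7.3e-07, limma). With the deposited scanner file ZM_00841_1, ZM_34020_1 and ZM_41977_1 had log2 changes of 6.02, 5.77 and -4.14 and adjusted p of 0.051, 0.055 and 0.12, the highest of their 23 alternatives, and the lowest was 1.5e-10.

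No slide held both groups with flagged samples, and with slide as a term over the anther samples, linked through early PMC, 3782 probes were called. The count was 5152 with only the groups compared, 3464 with the deposited scanner file, 2476 with 75th percentile scaling and 2379 with equal summed signal.

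**Figure D3:**
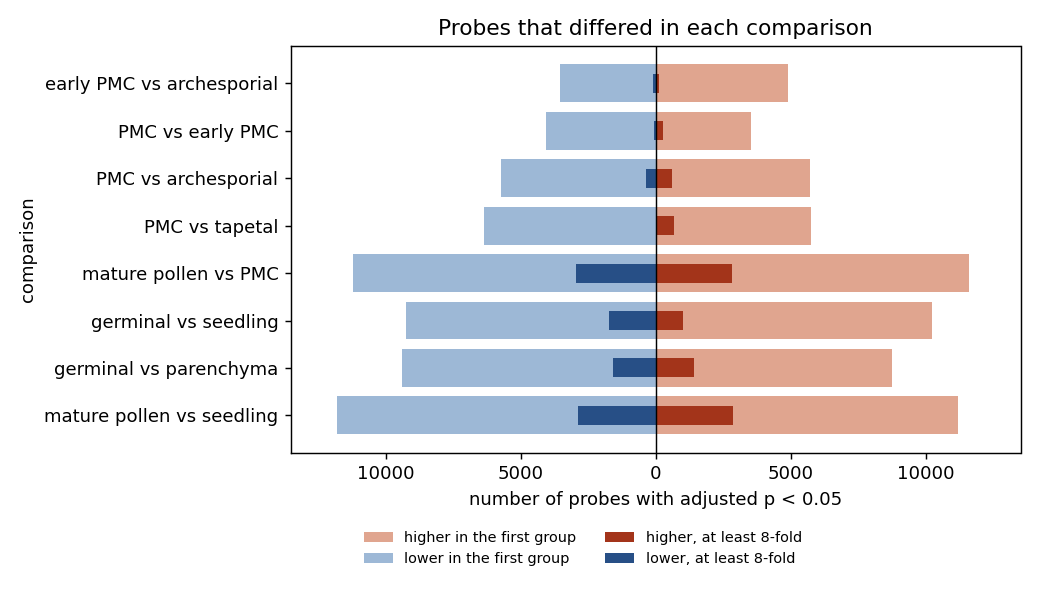
Number of probes with an adjusted p under 0.05 (horizontal axis) that were higher (right) or lower (left) in the first-named group of each comparison (vertical axis), with darker inner bars for probes changed at least 8-fold. Mature pollen differed from PMC in 22779 probes and from seedling in 23009, and PMC against tapetal cells had 685 probes at least 8-fold higher and 10 at least 8-fold lower.

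PMC and tapetal cells of the same anther length are the neighbouring germinal and somatic cell types of the anther locule. PMC had higher levels of 5752 probes and lower levels of 6353 than tapetal cells, 12105 of 39497 (30.6%; limma). The changes were uneven in size, since 685 probes were at least 8-fold higher in PMC and 10 at least 8-fold higher in tapetal cells. The latter count was 5, 64 and 4 without PMC replicates 1, 2 and 3, and 1, 64 and 14 without tapetal replicates 1, 2 and 3. ZM_13017_1, with the sequence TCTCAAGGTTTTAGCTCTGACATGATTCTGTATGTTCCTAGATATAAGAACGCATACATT, was at 15.59 ± 0.33 in PMC and 10.39 ± 0.15 in tapetal cells (SD, n = 3 each), a log2 difference of 5.20 ± 0.30 (SE, adjusted p = 6.9e-09, limma). The other 5 groups had it between 10.11 and 12.61. ZM_34020_1 was higher in PMC by 5.09 ± 0.67 log2 units (SE, adjusted p = 2.2e-05, limma), and by 2.35 with an adjusted p of 0.34 with the deposited scanner file, in a range of 6.9e-09 to 0.34 over 24 alternatives. The largest differences in favour of tapetal cells were smaller. ZM_13309_1 was at 11.63 ± 1.40 in PMC and 14.66 ± 0.89 in tapetal cells (SD, n = 3 each), a log2 difference of -3.03 ± 0.74 (SE, adjusted p = 0.0045, limma). ZM_15040_1 had a log2 difference of -3.13 ± 0.88 (SE, adjusted p = 0.012, limma), which was -2.63 with an adjusted p of 0.07 without tapetal replicate 3, in a range of 9.2e-06 to 0.07 over 24 alternatives.

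With slide as a term 13393 probes were called and within slide 1, which holds 2 PMC and 3 tapetal samples, 9171. The count was 6250 after loess and Aquantile, with a share of higher probes of 64.6% against 47.5%, and 7304 with the deposited scanner file, and the 8-fold counts were 174 and 68 with that file and 2072 and 657 on Agilent's processed signals.

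Mature pollen is the male gametophyte that forms after the meiosis of PMC. It had higher levels of 11588 probes and lower levels of 11191, 22779 of 39497 (57.7%; limma). Probes above background in every flagged pollen sample and in no flagged PMC sample numbered 3004, of which 2604 were called higher, and 2917 showed the opposite, of which 2492 were called lower. ZM_09684_1, with the sequence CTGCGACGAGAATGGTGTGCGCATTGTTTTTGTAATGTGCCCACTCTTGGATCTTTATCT, was at 18.69 ± 0.06 (SD, n = 3) in pollen and not well above background in PMC, at least 3360-fold higher (adjusted p = 5.3e-16, limma). ZM_12833_1 was at least 2650-fold higher in pollen (adjusted p = 5.3e-16, limma). In the other direction, ZM_11372_1, with the sequence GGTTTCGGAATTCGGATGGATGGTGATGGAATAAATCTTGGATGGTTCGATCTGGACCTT, was at 18.47 ± 0.19 (SD, n = 3) in PMC and not well above background in pollen, at least 2460-fold lower there (adjusted p = 4.1e-12, limma). ZM_25769_1 was at least 2510-fold lower in pollen (adjusted p = 1e-11, limma).

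PMC replicates 2 and 3 share no slide with mature pollen, and the slide of PMC replicate 1 is unknown, so slide and group cannot be told apart. With slide as a random block 21272 probes were called. The count was 9464 with 75th percentile scaling, where the median of all probes moved to 1.01 log2 units, and 12301 with equal summed signal, where it moved to -0.74 and 16.4% of the calls were higher in pollen against 50.9%.

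The germinal stages together were set against seedling and parenchyma to separate germinal from somatic transcripts. Against seedling, the mean of the 3 germinal stages was higher for 10219 probes and lower for 9249, 19468 of 39497 (49.3%; limma). ZM_11372_1 was at 17.05 ± 0.70 in archesporial cells, 18.07 ± 0.35 in early PMC and 18.47 ± 0.19 in PMC, against 7.04 ± 0.13 in seedling (SD, n = 3 each), a log2 difference of 10.43 ± 0.42 (SE, adjusted p = 7.3e-12, limma). ZM_03836_1 was not well above background in seedling. Its fitted log2 difference of 10.14 ± 0.37 (SE, adjusted p = 2.5e-12, limma) was taken against background signal. Tapetal cells held both at intermediate levels of 14.76 ± 1.58 and 13.89 ± 1.36 (SD, n = 3 each). ZM_13520_1 was at 17.80 ± 0.27 (SD, n = 3) in seedling and at 6.92 to 7.43 in the germinal stages, a log2 difference of -11.02 ± 0.28 (SE, adjusted p = 5.9e-14, limma). ZM_03053_1 had a log2 difference of -10.51 ± 0.36 (SE, adjusted p = 1.2e-12, limma) and was at 17.32 in parenchyma and 14.18 in mature pollen.

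**Figure D4:**
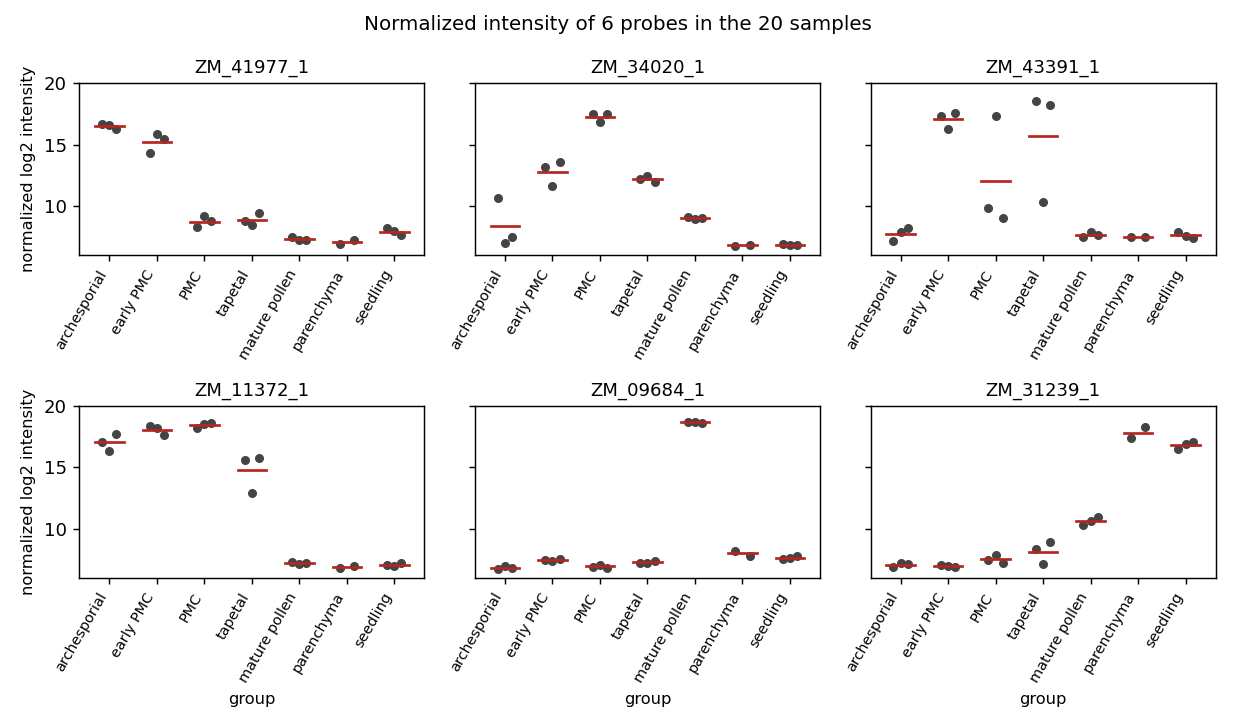
Normalized log2 intensity (vertical axis) of 6 of the named probes in each of the 20 samples (points) by group (horizontal axis), with a line at each group mean. ZM_41977_1 falls from early PMC (15.22) to PMC (8.73), ZM_34020_1 rises over the germinal stages, ZM_43391_1 varies by more than 7 log2 units among PMC and among tapetal samples, and ZM_11372_1, ZM_09684_1 and ZM_31239_1 are highest in germinal cells, mature pollen, and parenchyma with seedling.

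Against parenchyma, the germinal mean was higher for 8762 probes and lower for 9411, 18173 of 39486 (46.0%; limma). ZM_11372_1 and ZM_27347_1 were not well above background in parenchyma. Their fitted log2 differences of 10.94 ± 0.45 and 10.71 ± 0.74 (SE, adjusted p = 6.1e-12 and 3.3e-09, limma) were taken against background signal. ZM_31239_1 was at 17.84 ± 0.65 (SD, n = 2) in parenchyma and 16.85 ± 0.29 (SD, n = 3) in seedling, with a log2 difference of -10.70 ± 0.32 between germinal cells and parenchyma (SE, adjusted p = 2.1e-13, limma). ZM_06937_1 was at 17.55 ± 0.23 (SD, n = 2) in parenchyma and well above background in 1 of the 7 flagged germinal samples, so its fitted log2 difference of -10.62 ± 0.51 (SE, adjusted p = 4.3e-11, limma) was taken largely against background signal.

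The 7 flagged germinal samples share no slide with either tissue, and the slides of archesporial replicate 1 and PMC replicate 1 are unknown, so slide and group cannot be told apart. Slide as a random block gave 18318 and 17577 calls, and the deposited scanner file 11623 and 5805. With 75th percentile scaling the medians of all probes moved to 1.32 and 1.29 log2 units, the share of higher probes was 77.8% against 52.5% for seedling (64.8% after loess and Aquantile) and 67.4% against 48.2% for parenchyma, and parenchyma had 5635 calls, and equal summed signal gave 10904 and 4628.

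Mature pollen and seedling shared arrays, so their comparison was free of slide. Pollen had higher levels of 11203 probes and lower levels of 11806, 23009 of 39497 (58.3%; limma). ZM_18494_1 was at 18.42 ± 0.07 in pollen and 7.21 ± 0.17 in seedling (SD, n = 3 each), a log2 difference of 11.29 ± 0.24 (SE, adjusted p = 4.4e-15, limma), and ZM_09684_1 differed by 11.08 ± 0.22 (SE, adjusted p = 4.4e-15, limma). ZM_06527_1 and ZM_31239_1 had log2 differences of -7.10 ± 0.35 and -6.70 ± 0.40 (SE, adjusted p = 3.1e-11 and 4.4e-10, limma). Pollen was always Cy5 and seedling always Cy3, so the dye term came from the other groups, and the fit within slide 3 gave 20271 calls. With the replicate number as a fixed term the count was 23230. The term is common to all 7 groups, so it is not a term for the arrays that pollen and seedling shared. With 75th percentile scaling the median of all probes moved to 2.06 log2 units and 75.9% of the calls were higher in pollen, against 48.7%.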

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

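The tests of the scanner file and of the pollen signal were chosen only after the results were seen. The tests of PMC and tapetal transcripts were set before their values were seen, but after the 8-fold counts of that comparison, and reading them against the narrowest as well as the widest reference sample was chosen afterwards.

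The scanner file deposited under archesporial replicate 1 and PMC replicate 1 holds signal that the comparisons used only as an alternative; 61.8% of probes were well above background in the channel labelled archesporial and 61.6% in the channel labelled PMC, with no control sample to set them against. A poor scan of the right RNA is argued against, since the archesporial channel correlated with parenchyma samples at 0.846 or more and with archesporial samples at no more than 0.713. An exchange among the channels used is excluded by the values that raised the question, since the value table columns of these 2 samples equalled a channel at no more than 1.46% of spots, against 100% for the exchanged tapetal columns. The 2 channels that carried no sample of this series were not compared, so a match of the columns there stays open. Their dyes are those labelled for the 2 samples. If the columns matched, both samples would lie on slide 1, and the statements on slide would change. A file from another hybridisation may be the source of the deposited data, and stays open too. The channels' highest correlations with their own groups, 0.713 and 0.624, lay below those between the other 2 samples of each group, 0.943 and 0.918, but so did those of the value table columns, at 0.861 and 0.910, and no biological explanation was tested.

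Transcripts that mark PMC or tapetal cells against other groups were also measured in the other of the pair. A set of 23 probes was on in the 3 germinal stages, off in mature pollen, parenchyma and seedling, and at a mean of at least 12 log2 units in PMC. Of these, 18 were called lower and 1 higher in tapetal cells. Their medians were -3.68, -3.15 and -3.81 log2 units against PMC (early PMC -2.29, archesporial cells -4.51), but all were above background in every tapetal sample. The PMC values that chose the probes also enter this comparison, which favours lower values elsewhere, so the distance may be overstated. Probes on in all 7 groups at the same PMC brightness had a median of -0.62. Quantile normalization takes out a general dimness beforehand, and these probes were chosen as on in tapetal cells. Whether low signal in the tapetal samples adds to the distance is therefore not decided. PMC RNA carried into the tapetal samples at 1 share per sample cannot be told apart from transcription in both cell types, since the interquartile ranges of the distances were 1.51, 1.65 and 2.58 times the widest PMC range, on both sides of the limit of 2 set for the test. In turn, 318 probes were at least 8-fold higher in tapetal than in archesporial cells and early PMC. For them PMC samples had medians of -1.35, -1.71 and -1.44 against tapetal cells, whose values also chose the probes. Tapetal RNA in the PMC samples may explain this. The lowest range, in PMC replicate 2, was 0.611 times the widest tapetal range, in replicate 2, and 2.27 times the narrowest, in replicate 1. That test therefore does not decide, and transcription in both cell types stays open, untested. PMC replicate 2 and tapetal replicate 2 shared an array. For ZM_43391_1, ZM_00818_1, ZM_42769_1 and ZM_43513_1 each lay nearer the other replicates of the opposite cell type than those of its own. ZM_42506_1, ZM_09122_1 and ZM_00841_1 were free to show this pattern and did not. ZM_13017_1 and ZM_34020_1 could not show it, since their naming required every PMC sample to lie above every tapetal sample. The cause of the pattern was not tested.

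The concentration of the pollen signal in few probes was weighed against 3 technical explanations. The Cy5 dye is argued against, since the highest share among Cy5 samples of other groups was 41.7%, below the 69.9% of the lowest pollen sample by more than the pollen range. The arrays and slide are argued against by the seedling samples on the same arrays, with at most 36.5%. Dim hybridisation may contribute and stays open, because the 40.8% of PMC replicate 3, with a median spot of 69 against 78 to 80 in pollen, comes from 1 sample that was brighter at the 75th percentile, at 395 against 175 to 192. Uneven amplification of the pollen RNA and a transcript population dominated by fewer species were not tested and stay open too.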

How the results depend on the processing

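The alternatives chosen only after the data were seen were the deposited scanner file, leaving out archesporial 1 and PMC 1, treating them as 1 array, equal summed signal, and those of the group-enriched probes. Of the alternative values of the 8 comparisons and 7 detection counts, 207 stayed within 1.5 times the reported value and 23 did not. This compares counts, not which probes were called. For germinal cells against seedling, 75th percentile scaling gave 19873 calls, of which 13192 were reported calls in the same direction. For early PMC against archesporial cells, processed signals gave 8478 calls with 5954 shared in this way, and normexp offset 16 gave 8459 with 8210 shared. Among the alternative values of named probes, 770 kept their call and direction, 22 lost the call and 0 reversed.

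With 75th percentile scaling, PMC against early PMC had 1346 calls, PMC against archesporial cells 2476, mature pollen against PMC 9464 and germinal cells against parenchyma 5635. With equal summed signal the first 3 had 1294, 2379 and 12301, and germinal cells had 10904 against seedling and 4628 against parenchyma. Under these scalings the median log2 change of all probes was 0.59 and 0.53 in PMC against tapetal cells (-0.04 as reported), 1.01 and -0.74 in pollen against PMC (0.01), 1.32 and 1.17 in germinal cells against seedling (0.08), 1.29 and 0.80 against parenchyma (0.03), and 2.06 and 0.11 in pollen against seedling (-0.01). With equal summed signal it was -0.17 in early PMC and -0.21 in PMC against archesporial cells (0 in both). On Agilent's processed signals it was 0.27 for germinal cells and -0.14 for pollen against seedling, and after loess and Aquantile 0.23 for germinal cells against seedling. Loess and Aquantile, with 16 samples, gave 2869 calls for early PMC against archesporial cells and 6250 for PMC against tapetal cells.

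The deposited scanner file gave 3775, 1651, 3464 and 7304 calls for early PMC against archesporial cells and for PMC against early PMC, archesporial and tapetal cells, and 11623 and 5805 for germinal cells against seedling and parenchyma. Without both samples the 8 counts were 9051, 8159, 11636, 12609, 23099, 20817, 19498 and 24318, in the order of the report. With slide as a term, PMC had 4117 calls against early PMC and 3782 against archesporial cells. Within slide 1, limma called 0 probes between PMC and the lone early PMC sample, with 7755 at an unadjusted p under 0.05. With only the groups compared, early PMC against archesporial cells had 1 call at a block correlation of -0.87, with 5917 at an unadjusted p under 0.05, and PMC against archesporial cells had 5152. Quantile normalization gives all channels the same distribution of values, which favours median changes near 0 and similar counts of higher and lower probes. The balance of the reported counts is therefore no evidence that general transcript levels were equal. The raw 75th percentile was 175 to 192 in pollen samples, against 395 (PMC replicate 3) to 2260 (seedling replicate 2) in the other groups. Which scaling is right was not tested, nor were the causes of the changes with source of values, slide or samples fitted.

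Leaving out each sample in turn gave 5870 to 8709 calls for early PMC against archesporial cells and 4611 (without early PMC replicate 3) to 7333 for PMC against early PMC. The ranges were 9064 to 12031 for PMC against archesporial cells, 9640 to 11082 for PMC against tapetal cells, 20424 to 22378 for pollen against PMC, 17021 to 20692 and 13614 to 19361 for germinal cells against seedling and parenchyma, and 21069 to 21628 for pollen against seedling. With the replicate number as a fixed term common to all groups, there were 8486, 7291, 11213, 12267, 22751, 19266, 17221 and 23230 calls in the order of the report. Set tests and the choice of 1 probe per gene were not run, since no probe has a gene name. Signals under the background floor limit every fold against a group that is off.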

Other observations

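The group-enriched probes, the course over the 3 germinal stages and the likeness to seedling were chosen only after the data were seen. The splits of the samples were planned.

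Probes called higher, at least 2-fold, than in each other group numbered 4937 of 39497 (12.5%) in mature pollen. There were 1804 in parenchyma, 1792 in seedling, 785 in PMC, 711 in tapetal cells, 259 in archesporial cells and 229 in early PMC. The pollen probes had a median log2 intensity of 11.31 in pollen and 7.60 to 7.71 elsewhere, while the tapetal probes had 12.32 in tapetal cells and 10.59 in PMC. Of the 4937 pollen probes, 160 (3.24%) were above background in every pollen sample and in no flagged sample of any other group. By the same rule 4 of the PMC probes and 0 of the tapetal probes were on in their group alone. In all 3 germinal stages 381 probes were higher than in the other 4 groups, and in the 4 anther cell groups 781 were higher than in pollen, parenchyma and seedling. These 2 counts were 109 and 254 with 75th percentile scaling and 11 and 29 with the deposited scanner file. With 75th percentile scaling the 7 groups had 2897 (mature pollen), 152 (parenchyma), 584 (seedling), 137 (PMC), 313 (tapetal), 34 (archesporial) and 36 (early PMC). With equal summed signal the pollen count was 1154, and with the deposited scanner file the counts of archesporial cells and PMC were 12 and 65. None of 99 shuffles of the 20 labels reached the real total of 10517 probes over the 7 groups, which with the real labels makes 1 of 100. Chance is excluded for this total at this number of shuffles, and the highest other total was 818. The counts of single groups were not tested by shuffling, and those of PMC, tapetal cells, archesporial cells and early PMC lie below 818. The shuffles move labels across slides, in which the groups are nested, so they do not exclude an effect of slide.

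Over the 3 germinal stages, 1371 probes were called higher in early PMC than in both archesporial cells and PMC, and 480 lower than in both. A rise at both steps was called for 650 probes and a decrease at both for 373. If the steps were independent, 504, 316, 436 and 365 probes would be counted. Both steps use the early PMC samples, so errors in these alone push the counts of opposite changes up. How many of the 1371 come from that is not known. In 20 simulations without any difference, the fold changes of the steps had a mean correlation over probes, which are not independent replicates, of -0.488, against -0.0805 in the data. The simulated value follows from the early PMC samples shared by both steps when nothing differs. The data hold differences that the simulations lack, so the gap does not tell how large the shared error is. Of the 11435 probes called between PMC and archesporial cells, 4998 were also called at the step to early PMC, 4740 at the step from early PMC and 2720 at neither.

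The mean Spearman correlation with the seedling samples, over tested probes, was 0.689, 0.762 and 0.761 for the archesporial samples, 0.639, 0.687 and 0.691 for early PMC and 0.638, 0.626 and 0.621 for PMC. The differences between the stages were not tested, and the archesporial and PMC samples with flags lay on different slides.

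For germinal cells against seedling, 1 of 100 splits of the 12 samples gave as many calls as the real one, which had 19468. Chance is excluded here, but an effect of slide is not, since all seedling samples lay on slide 3. The highest other split had 10427 calls and kept seedling replicates 2 and 3 together with archesporial replicate 3, so it shares 2 of its 3 seedling labels with the real one. The other comparisons of 3 against 3 samples have 10 splits each, too few for a share under 0.05. The real and the highest other counts were 8455 and 54 for early PMC against archesporial cells, 7580 and 61 for PMC against early PMC, 11435 and 203 for PMC against archesporial cells, 12105 and 324 for PMC against tapetal cells, 22779 and 1 for mature pollen against PMC, and 23009 and 2 for mature pollen against seedling.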
